A study of Mus musculus with 9 samples.

How the data were processed

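Per the labels' protocols, lung RNA of BALB/c mice was isolated with Trizol and 3 µg of total RNA per library went into NEBNext Ultra libraries for Illumina sequencing. The submitters' processing notes name FastQC, cutadapt, STAR, HTSeq and DESeq2 and the build mm10, without versions or settings, and the RNA selection, read layout, gene annotation and strand setting are not given in the sources used here. The authors deposited whole-number counts per gene and library for 21983 gene symbols, with no normalization, and these counts were the input of every test here. Per the file headers, the authors also deposited tables of 3 comparisons with log2 fold changes, p-values and adjusted p-values. In these deposited tables every gene had a p-value under 0.05 and a log2 fold change of at least 1 in size. They hold 36 further columns of values per library, which were not used here. The authors' log2 fold changes and p-values were used only for counts of listed genes and for signs. Their tables compare the same libraries and list only genes past these limits, so the same sign here is no separate support.

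Samples were grouped by the group name in each label into control, asthma and BSYQF, with 3 libraries each and the replicate numbers of the labels. The groups, the tests, 38 tested gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Counts were filtered with filterByExpr and scaled with TMM (factors 0.914 to 1.07), and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and its default dispersion method, glmQLFTest) in 1 model of the 3 groups without a replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14739 genes tested. The SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.244. The fixed design named no dispersion method, and the results of both methods had been seen when edgeR's default was taken as the main one. The newer method, an alternative added after the data were seen, called 1944, 1 and 269 genes in asthma against control, BSYQF against asthma and BSYQF against control.

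Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists within a comparison. Of these 14, 15 and 19 passed in asthma against control, BSYQF against asthma and BSYQF against control (9, 10 and 14 higher, 5 each lower). With an estimated correlation 0 passed in each comparison, where 3, 5 and 5 had an unadjusted p under 0.05. The fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, passed 16, 1 and 9 lists. The 1 in BSYQF against asthma was squamous epithelium (adjusted p = 0.0105). In asthma against control fry kept 11 of the 14 camera lists, losing MHC class II, ciliated cell and endothelial genes (adjusted p = 0.0798, 0.124 and 0.0989). It also passed the type 2 cytokine axis, eosinophil, dendritic cell, matrix protease and squamous epithelium lists, which camera did not. Of the genes on the lists, 446 of 457 were in the count table and 408 were tested. The list of sex-linked genes served as a check of the table and was not tested. Some lists share genes.

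The text names, for each comparison, up to 10 called genes with the largest rise and 10 with the largest fall among those with a mean of at least 1 CPM in the higher group and no overlap between the groups. It also names the 4 members with the smallest p-values of each list that passed or had at least 2 called members, genes called in both asthma against control and BSYQF against asthma, and, where fewer than 5 genes were called, the 10 with the smallest p-values. Unnamed gene models and antibody or T cell receptor segments were left out of this rule, and a few genes of the study's topic (among them Muc5ac, Clca1, Chil3, Retnla, Col1a1, Acta2 and Tgfb1) were always named. The text picks from the genes so named. Genes named outside the rule in the closing section were chosen after their values were seen.

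Coordinates are from GENCODE vM21 on GRCm38 (mm10), matched by symbol, 1-based; 21896 of 21983 symbols matched a single gene, and 14683 of the 14739 tested. Gene families with close copies, such as the Saa, Mcpt, Clca, Chil, Ear, Rnase2 and MHC genes, and overlapping genes are uncertain, since the handling of shared reads and of strand is not stated. The surfactant gene Sftpb had 7 to 24 counts per library while Sftpc had 238614 to 429543, so a low count in the deposited table may be a limit of the counting. Kif11 likewise had 0 counts in every library, where Mki67 of the same proliferation list reached 2185. Total counts per library were 16286385 to 22819199, and 3 counts correspond to 0.134 to 0.202 CPM. Of 5 antibody variable segments listed, 1 was tested and 0 were called. The antibody constant genes Igha, Ighg1, Ighg2b, Ighg3 and Ighe were not in the count table. The removal of antibody genes took out symbols beginning with Igh, Igk or Igl, which may include other genes.

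The procedures were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 14447 tested by edgeR and limma voom and 14730 by DESeq2. The changed genes were drawn only from those above a minimum expected count, so the recoveries do not cover genes with few counts. In simulated asthma against control, edgeR recovered 37% of the 2-fold and 87% of the 4-fold changes with 5 false calls, and in simulated BSYQF against asthma 44% and 88% with 4 false calls. In simulated BSYQF against control, where no gene was changed, it made 0 false calls, limma voom made 0 and DESeq2 made 12, after 39 and 34 in the other comparisons. A simulated 2-fold rise of the extracellular matrix list was called and 0 other lists were. Genes were drawn independently, so these counts lack the correlation within lists, estimated at 0.40 for the matrix list in the real libraries. They cannot show how often camera calls other lists falsely in real libraries. Alternatives were DESeq2 1.42.0, limma voom with sample weights, other scalings and filters, removal of antibody genes, fits on 6 libraries, a replicate block, and omission of each library in turn. Unchanged or treated groups were simulated in 30 draws for the shared asthma and control libraries.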

Results

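Lung RNA was sequenced from BALB/c mice, an inbred laboratory strain, in 3 groups with 3 libraries each: normal mice given saline by mouth (control), mice with a chronic asthma model given saline (asthma), and mice with the same model given Bu-Shen-Yi-Qi formula, a Chinese herbal mixture (BSYQF). The formula was given by mouth from day 14 at a dose of 20 g of raw herbs per kg. The series title names regulated gene targets of the formula against airway remodelling as the aim. Counts assigned to genes totalled 16286385 to 22819199 per library, with asthma replicate 3 the deepest, and 15476 to 16486 genes had a count. After filtering, 14739 genes were tested. Levels are in CPM, counts scaled by the size of each library, as mean ± SD over 3 libraries, and changes are log2 fold changes ± SE with adjusted p-values from edgeR's quasi-likelihood test. The labels call the libraries replicates without saying that each came from a different mouse, so p-values measure the spread between these libraries, which may be technical in part. On the first principal component, which held 51.6% of the variance, the controls lay at −51.9, −56.7 and −43.2, and asthma replicates 1, 2 and 3 at 51.9, 76.0 and 1.77. BSYQF replicates 1, 2 and 3 lay at 40.5, 1.20 and −19.6. Asthma replicate 3 and BSYQF replicate 1 thus stood apart from the other libraries of their groups. Asthma replicate 2, the furthest from control, differed in its make-up: its top 10 genes held 17.1% of its counts (7.53 to 13.7% elsewhere), its top gene was the mitochondrial mt-Co1 (4.43%) where the others had Scgb1a1, and it had the fewest genes with a count. RNA quality as a cause was not tested.

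The comparison of asthma with control asks what the model changes in the lung. Several mucus, alternatively activated macrophage and antibody-secreting cell genes were much higher in the asthma lungs. The gene of a secreted airway defence protein and several genes of fat and heart-type muscle were much lower. The camera calls for the mucus, macrophage, plasma cell, fat and cardiac lists, given below, were lost at adjusted p = 0.39 with an estimated correlation. Clca1, a secreted protein of goblet cells, rose from 1.71 ± 1.05 to 1625 ± 1606 CPM (log2 fold change 9.88 ± 1.88, adjusted p = 0.0188). Retnla, a product of alternatively activated macrophages, rose from 39.8 ± 36.1 to 4042 ± 1955 CPM (6.66 ± 1.11, adjusted p = 0.0108). Jchain, which joins the chains of polymeric antibodies, rose from 115 ± 97.9 to 2861 ± 488 CPM (4.64 ± 0.53, adjusted p = 0.00293). Bpifa1, a secreted defence protein of the airway epithelium, fell from 555 ± 104.96 to 44.1 ± 35.1 CPM (-3.65 ± 0.53, adjusted p = 0.00825). In mm10 coordinates, Clca1 lies on chromosome 3 from 145003817 to 145032776 on the minus strand, Jchain on chromosome 5 from 88519809 to 88527891 on the minus strand, and Bpifa1 on chromosome 2 from 154142880 to 154149219 on the plus strand. All 3 are annotated as protein coding.

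In the list of mucus and goblet cell genes, 10 of 12 measured members rose over all genes tested and 12 rose when adjusted over the list alone. They included Muc5ac, the gel-forming mucin of the airway surface, at 4.07 ± 0.87 (from 1.42 ± 0.454 to 24.1 ± 13.3 CPM), Muc5b, another gel-forming mucin, at 2.99 ± 0.55, and Slc26a4, the anion exchanger pendrin, at 4.92 ± 0.77. Among type 2 effector and alternatively activated macrophage genes, 6 of 14 rose, or 12 adjusted over the list alone, among them Ccl22, a ligand of CCR4, at 2.74 ± 0.42. Chil3, a chitinase-like protein of macrophages, did not pass at 4.10 ± 1.21 (adjusted p = 0.0563). Both lists rose against the other genes (camera adjusted p = 1.0e-07 and 1.0e-06), and both calls were lost at adjusted p = 0.39 with an estimated correlation. The goblet list stood 3.74, 4.62 and 2.57 above the control mean on the log2 scale in asthma replicates 1, 2 and 3, so replicate 3 was the lowest. Of the type 2 cytokine axis, 2 of 14 members rose and 5 did when adjusted over the list alone. The alarmin Il33 rose by 1.78 ± 0.30 and Socs1, an inhibitor of cytokine signalling, by 1.64 ± 0.47, while the list itself did not pass (adjusted p = 0.363). Il4, Il5 and Il13 had at most 11, 10 and 16 counts in any library and were not tested. Epx, the eosinophil peroxidase, had at most 3 counts, and no member of the 4 measured eosinophil genes was called (list adjusted p = 0.233). A low count in the deposited table may be a limit of the counting, so it does not show that these transcripts were absent. Of 12 mast cell and basophil genes, 4 rose over all genes tested, and adjusted over the list alone 4 rose and 1 fell. They included the mucosal mast cell proteases Mcpt2 (5.84 ± 1.26) and Mcpt1 (from 0.0750 ± 0.0651 to 31.7 ± 33.9 CPM, with too few control counts for a fold), though the list did not pass (adjusted p = 0.0597).

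Immune cell genes were higher in several groups. Of 8 plasma cell genes 7 rose over all genes and 7 adjusted over the list alone, with Mzb1, a chaperone of antibody secretion, at 3.90 ± 0.49. Of 8 interstitial macrophage genes 7 rose over all genes and 8 adjusted over the list alone. Ms4a7 rose by 2.69 ± 0.25 (adjusted p = 0.00238) and C1qb, a chain of the complement component C1q, by 1.97 ± 0.24. Of 16 inflammatory cytokines and chemokines 9 rose over all genes and 12 adjusted over the list alone, including Ccl8 at 5.22 ± 0.77 and the monocyte attractant Ccl2 at 4.25 ± 0.67. Of 15 proliferation genes 13 rose over all genes and 15 adjusted over the list alone, with Birc5 at 2.96 ± 0.42 and Mki67 at 2.52 ± 0.43. The 4 lists rose against the other genes, with adjusted p = 1.3e-06, 1.0e-07, 1.0e-07 and 1.6e-08 in that order, and each call was lost at adjusted p = 0.39 with an estimated correlation. MHC class II genes rose as a list (adjusted p = 0.00537; adjusted p = 0.49 with an estimated correlation), with 1 of 9 members rising over all genes and 6 adjusted over the list alone. NRF2 antioxidant genes also rose (adjusted p = 0.00404; adjusted p = 0.39 with an estimated correlation). In that list 5 of 9 members rose over all genes, and adjusted over the list alone 7 rose and 1 fell. The cystine transporter Slc7a11 rose by 3.55 ± 0.50 and haem oxygenase Hmox1 by 3.79 ± 0.65. Ciliated cell genes rose (adjusted p = 0.0117; adjusted p = 0.55 with an estimated correlation), with 5 of 14 members rising over all genes and 7 adjusted over the list alone. The ciliated list mean lay 0.08, 0.83 and 0.63 from the control mean in asthma replicates 1, 2 and 3, with replicate 1 inside the range of the controls. Foxj1, the transcription factor of motile cilia, rose by 0.86 ± 0.23.

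A few matrix genes, which bear on airway remodelling, changed. Of 24 extracellular matrix genes 4 rose over all genes, and adjusted over the list alone 4 rose and 1 fell. Beside this, 1869 of all 14739 genes were called, 1213 of them higher. The list mean lay 0.54, -0.10 and 0.12 from the control mean in asthma replicates 1, 2 and 3. Replicates 2 and 3 were inside the range of the controls. Tenascin C (Tnc) rose by 2.77 ± 0.56, versican (Vcan) by 1.83 ± 0.35, the crosslinking enzyme Lox by 1.36 ± 0.30 and the collagen Col3a1 by 0.90 ± 0.25, and the list did not pass (adjusted p = 0.424). In the 9 fits that left out a library, Tnc was called in 4, Vcan in 6, Lox in 5 and Col3a1 in 3. Of 16 matrix proteases and inhibitors 6 rose over all genes, and adjusted over the list alone 8 rose and 2 fell (list adjusted p = 0.0675). The inhibitor Timp1 rose from 4.04 ± 1.36 to 305 ± 214 CPM (6.23 ± 0.82) and the membrane protease Mmp14 by 1.58 ± 0.24. In the TGF-beta list 4 of 17 members rose and 2 fell over all genes, and 4 rose and 4 fell adjusted over the list alone, with Inhba, the activin A subunit, at 3.99 ± 0.58 and Ltbp4, which binds latent TGF-beta, at -1.56 ± 0.27 (list adjusted p = 0.424). Col1a1 (0.62 ± 0.25, adjusted p = 0.111), the smooth muscle actin Acta2 (0.45 ± 0.25, adjusted p = 0.225) and Tgfb1 (0.42 ± 0.24, adjusted p = 0.235) did not pass. In the smooth muscle list 1 of 12 members fell, both over all genes and adjusted over the list alone (list adjusted p = 0.890).

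Fibroblast, alveolar type 1 cell and endothelial genes were lower as groups. Of 10 fibroblast genes 2 fell over all genes and 8 adjusted over the list alone (list adjusted p = 9.7e-05), with nephronectin (Npnt) at -1.32 ± 0.25. Of 8 alveolar type 1 cell genes 3 fell over all genes and 4 adjusted over the list alone (list adjusted p = 0.0235), with Clic5 at -1.11 ± 0.31. Of 13 endothelial genes 1 fell over all genes, the VEGF receptor Kdr at -1.29 ± 0.35, and 5 adjusted over the list alone (list adjusted p = 0.00150). The endothelial mean of asthma replicate 3 (-0.16) lay inside the range of the controls. These calls were lost at adjusted p = 0.39, 0.39 and 0.49 with an estimated correlation. Markers of tissue around or attached to the lung fell with them. Of 12 cardiac muscle genes, which mouse lung also expresses in its pulmonary veins, 9 fell over all genes and 11 adjusted over the list alone (adjusted p = 9.0e-07). The atrial light chains Myl4 and Myl7 fell by 2.38 ± 0.41 and 2.59 ± 0.52 on the log2 scale. Of 7 adipocyte genes 5 fell, over all genes and adjusted over the list alone (adjusted p = 0.00150), with adiponectin (Adipoq) at -5.78 ± 1.13 and Cfd at -4.99 ± 0.95. Lep, the fat hormone leptin, was at 3.996 ± 2.69 CPM in control and listed at 0 in the 3 asthma libraries. The cardiac and adipocyte calls were lost at adjusted p = 0.39 with an estimated correlation. Of 8 squamous epithelium genes only 4, Krt5, Krt14, Krt15 and Trp63, were measured. The basal cell keratins Krt5 (-4.13 ± 0.60) and Krt15 (-3.46 ± 0.59) fell over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.0543). With Krt4, Krt13, Krt6a and Sprr3 not tested, the list cannot show a loss of squamous tissue. In the list of 8 club cell genes, Bpifa1 fell and haptoglobin (Hp) rose by 1.08 ± 0.22, over all genes and adjusted over the list alone (list adjusted p = 0.675).

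Further lists did not pass by camera in this comparison. Among interferon response genes 2 of 15 rose and 1 fell, over all genes and adjusted over the list alone. The chemokines Cxcl9 and Cxcl10 rose by 3.12 ± 0.39 and 2.51 ± 0.50, and Ifit2 fell by 0.96 ± 0.23 (list adjusted p = 0.422). Of 8 dendritic cell genes 4 rose over all genes, with Fscn1 at 1.68 ± 0.27, and adjusted over the list alone 4 rose and 1 fell (list adjusted p = 0.0675). Of 12 alveolar macrophage genes 2 rose and 1 fell over all genes, and 3 rose and 2 fell adjusted over the list alone. The protease Ctsd rose by 1.29 ± 0.23 and Fabp4, which fat cells also express, fell by 2.63 ± 0.58 (list adjusted p = 0.563). The list adjusted p-values were 0.225 for B cell genes, 0.890 for T cell genes, 0.409 for cytotoxic and NK cell genes, 0.422 for neutrophil genes, 0.309 for alveolar type 2 cell genes and 0.838 for glucocorticoid response genes, in which the metallothioneins Mt1 and Mt2 rose by 2.12 ± 0.41 and 3.18 ± 0.57. They were 0.0893 for circadian clock genes, 0.424 for immediate early genes, 0.438 for aryl hydrocarbon receptor targets, 0.309 for skeletal muscle genes, 0.309 for erythroid genes and 0.363 for thymocyte genes. Over all genes, 1 alveolar type 2 cell gene rose, 1 clock gene and 1 aryl hydrocarbon receptor target fell, and of 7 skeletal muscle genes 1 rose and 2 fell. The median, mean and test differed in sign in the T cell list (median 0.03, mean −0.03), the alveolar macrophage list (0.33, −0.07) and the TGF-beta list (−0.21, 0.17, lower by the test).

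In all, 1869 of 14739 genes were called in asthma against control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1213 higher and 656 lower, and 1012 of these changed at least 2-fold (716 higher, 296 lower). The 3 libraries of the groups did not overlap in 5957 genes, 40.4% of those tested, where chance gives 10%. DESeq2 called 3258 genes and limma voom 4935, and calls fell to 438, 182 and 357 without control replicate 1, 2 or 3, to 171 and 248 without asthma replicate 1 or 2, and to 944 without BSYQF replicate 2, and rose to 4262 without asthma replicate 3. Of the 101 called genes that the naming rule picked, 27 were called in every one of the 9 fits that left out a library. Jchain and Bpifa1 were called in all 9, Retnla in 6, and Muc5ac and Clca1 in 4, Clca1 with log2 fold changes of 8.72 to 10.50 and an adjusted p of up to 0.0948. The authors' deposited table for this comparison listed 1746 genes, 1025 higher and 721 lower, of which 1435 had an adjusted p under 0.05 there. All 1649 of them that were tested here had the same sign, which the shared libraries and the limits of that table make all but certain, and 1011 were called here.

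**Figure D1:**
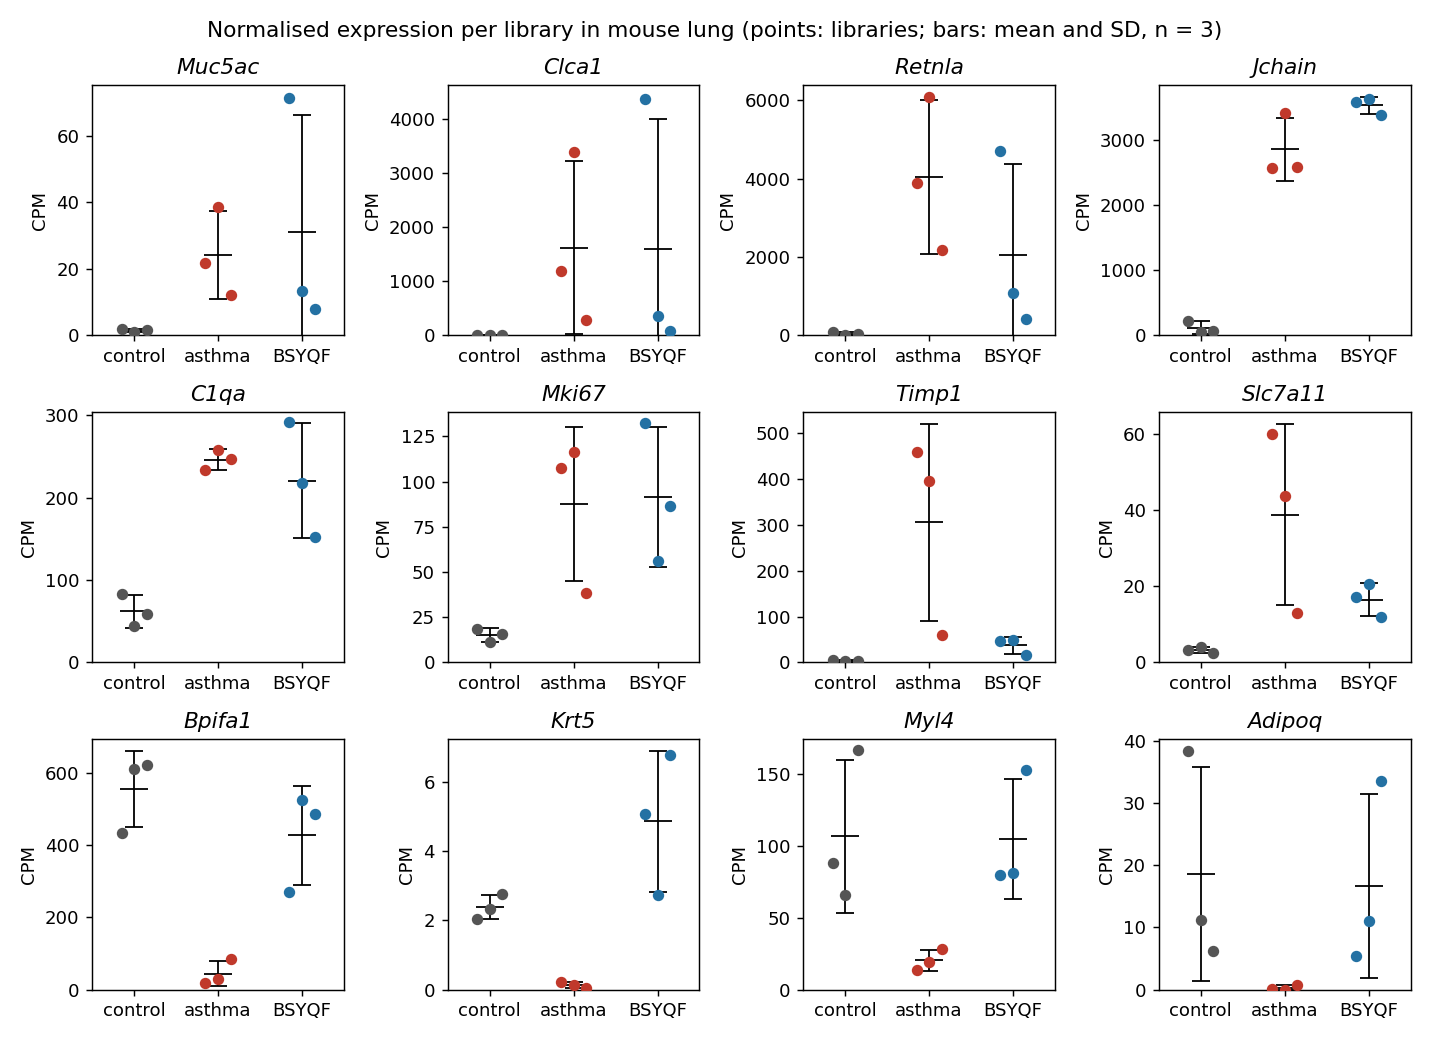
Normalised expression of 12 genes in CPM (linear axes starting at 0) for the control, asthma and BSYQF groups, with a point per library and bars for the mean and SD of 3 libraries, the lower bar ending at the axis where it would pass 0. Bpifa1 and Krt5 were lower in each asthma library than in every control and BSYQF library, Jchain lay far above control in both asthma and BSYQF, and Clca1 and Muc5ac spread widely within the BSYQF group.

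The comparison of BSYQF with asthma asks what the formula changes in asthmatic lung. Krt5, a keratin of airway basal cells, was the 1 gene called: it rose from 0.135 ± 0.0908 CPM in asthma to 4.86 ± 2.03 CPM with BSYQF (5.15 ± 0.60, adjusted p = 0.0431), beside 2.39 ± 0.359 CPM in control. The gene lies on chromosome 15 from 101707070 to 101712898 on the minus strand of mm10, and its counts were 4, 2 and 1 in the asthma libraries against 84, 47 and 130 in the BSYQF libraries. The fold thus rests on few asthma counts. The genes with the next smallest p-values did not pass. They included Krt15 (3.94 ± 0.59, adjusted p = 0.186), Bpifa1 (3.27 ± 0.52, adjusted p = 0.186; 427 ± 137 CPM with BSYQF), the muscle genes Myoz2, Mybphl, Dhrs7c, Ttn and Myl4 (log2 fold changes 1.86, 2.48, 3.17, 1.96 and 2.36, adjusted p = 0.186 to 0.209), and Clca3b (3.40 ± 0.60, adjusted p = 0.209). The mucus gene Muc5ac had a log2 fold change of 0.36 ± 0.73 (adjusted p = 0.886), Clca1 -0.02 ± 1.25 (adjusted p = 0.997), Retnla -0.97 ± 0.87 (adjusted p = 0.728) and Chil3 0.34 ± 1.07 (adjusted p = 0.935). The values were -0.34 ± 0.25 for Col1a1, -0.31 ± 0.25 for Acta2 and -0.12 ± 0.24 for Tgfb1, with adjusted p = 0.669, 0.698 and 0.886.

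As groups, genes of cardiac muscle, fat and T cells were higher with BSYQF, as were the 4 measured genes of the squamous epithelium list. These were Krt5, Krt14, Krt15 and Trp63, while Krt4, Krt13, Krt6a and Sprr3 were not tested. A rise of that list thus speaks for these 4 genes only. Cardiac muscle genes rose (adjusted p = 1.8e-15; adjusted p = 0.32 with an estimated correlation), as did adipocyte genes (4.1e-08; adjusted p = 0.32 with an estimated correlation) and squamous epithelium genes (3.6e-05; adjusted p = 0.17 with an estimated correlation). Of their 12, 7 and 4 members 0, 0 and 1 rose over all genes, where 1171 genes had an unadjusted p under 0.05, and 12, 5 and 2 rose adjusted over the list alone. Myl7 was at 11.8 ± 5.98 CPM in asthma and 75.9 ± 38.5 with BSYQF, and Cfd at 3.17 ± 2.43 and 101.71 ± 83.7. The cardiac list mean was -2.41, -2.16 and -1.55 from the control mean on the log2 scale in asthma replicates 1, 2 and 3, and -0.32, -0.06 and 1.01 in the BSYQF replicates. Skeletal muscle genes rose too (adjusted p = 0.0406; adjusted p = 0.35 with an estimated correlation), with 0 of 7 members called over all genes and 2 adjusted over the list alone. T cell genes rose (adjusted p = 1.5e-07; adjusted p = 0.35 with an estimated correlation), B cell genes rose (0.00385; adjusted p = 0.78 with an estimated correlation) and the thymocyte list rose (0.0398; adjusted p = 0.57 with an estimated correlation). Of that list only 3 of 7 members were measured, which other T cells also express. Their mean lay -0.03, -0.13 and 1.07 from the control mean in BSYQF replicates 1, 2 and 3 and -0.69, -0.11 and -0.55 in the asthma replicates, so the rise rests mostly on BSYQF replicate 3. None of the 10, 10 and 3 members of these lists was called over all genes, and 4, 1 and 1 rose adjusted over the list alone. Cytotoxic and NK cell genes did not pass (adjusted p = 0.203), with 8 of 9 lower. Cd4, the helper T cell co-receptor, had a log2 fold change of 0.90 ± 0.21 (adjusted p = 0.315) and Cr2, a complement receptor of B cells, 1.40 ± 0.40 (adjusted p = 0.466).

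Immediate early genes rose as a list (adjusted p = 1.4e-04; adjusted p = 0.52 with an estimated correlation), with 0 of 11 members called over all genes and 4 rising adjusted over the list alone. Egr3 was at 2.20 ± 0.41 (adjusted p = 0.209). Their mean lay 0.96, 1.11 and -0.24 from the control mean in BSYQF replicates 1, 2 and 3. Fibroblast genes rose (adjusted p = 0.00225; adjusted p = 0.57 with an estimated correlation), as did endothelial genes (0.0398; adjusted p = 0.84 with an estimated correlation), and none of their 10 and 13 members was called over all genes or adjusted over the list alone. NRF2 antioxidant genes fell (adjusted p = 6.7e-04; adjusted p = 0.50 with an estimated correlation). Of that list 0 of 9 members were called over all genes and 6 fell adjusted over the list alone. Hmox1 was at 497 ± 351 CPM in asthma and 88.4 ± 40.2 with BSYQF (-2.49 ± 0.61, adjusted p = 0.380). Matrix proteases and inhibitors fell (adjusted p = 0.0436; adjusted p = 0.42 with an estimated correlation), with 0 of 16 called over all genes and 2 falling adjusted over the list alone. Timp1 was at -3.02 ± 0.69 (adjusted p = 0.321) and Mmp14 at -0.99 ± 0.24 (adjusted p = 0.321). Extracellular matrix genes, type 2 effector genes and interstitial macrophage genes fell as lists, with adjusted p = 0.0398, 0.0398 and 0.0283, and adjusted p = 0.84, 0.84 and 0.59 with an estimated correlation. The extracellular matrix list mean lay 0.54, -0.10 and 0.12 from control in the asthma replicates and -0.25, 0.18 and 0.02 in the BSYQF replicates, so the libraries overlapped. Asthma replicate 3 lay above BSYQF replicates 1 and 2 in the fibroblast list mean (-0.43 against -0.71 and -0.56) and above all BSYQF replicates in the endothelial one (-0.16 against -0.45, -0.39 and -0.32). It lay below BSYQF replicate 2 in the NRF2 mean (0.55 against 0.63) and below BSYQF replicates 1 and 2 in the matrix protease mean (0.83 against 1.18 and 0.95), so these changes rest on asthma replicates 1 and 2. The asthma and BSYQF libraries also overlapped in the B cell, immediate early and type 2 effector means. No member of the extracellular matrix, type 2 effector and interstitial macrophage lists was called over all genes or adjusted over the list alone; Tnc was at -2.16 ± 0.54 (adjusted p = 0.380). Mucus and goblet cell genes did not pass (adjusted p = 0.245), nor did TGF-beta genes (0.822) or smooth muscle genes (0.282). The median, mean and test differed in sign in the erythroid list (median 0.32, mean 0.35, lower by the test), the chemokine list (0.21, −0.13), the type 2 cytokine axis (−0.15, 0.12) and the eosinophil list (−0.18, 0.05), none of which passed.

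With edgeR, 1 of 14739 genes was called in BSYQF against asthma and 1171 had an unadjusted p under 0.05, 559 higher and 612 lower. The groups did not overlap in 1437 genes, or 9.75%, where chance gives 10%. DESeq2 called 122 genes (98 higher, 24 lower) and limma voom 1, which was not Krt5. The Krt5 call was lost, with 0 genes called by edgeR and 547 to 2260 at an unadjusted p under 0.05, when any of control replicates 1, 2 and 3, asthma replicates 1 and 2 or BSYQF replicates 1 and 3 was left out. Its log2 fold change stayed at 4.68 to 5.78 over all 9 omissions. Without asthma replicate 3, 114 genes were called (64 higher, 50 lower), Krt5 among them. The authors' deposited table for this comparison listed 424 genes at an unadjusted p under 0.05 and at least a 2-fold change, 325 higher and 99 lower. Of these 77 had an adjusted p under 0.05 in that table, and the largest adjusted p in it was 0.851. All 360 of them that were tested here had the same sign, and 1 was called here.

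**Figure D2:**
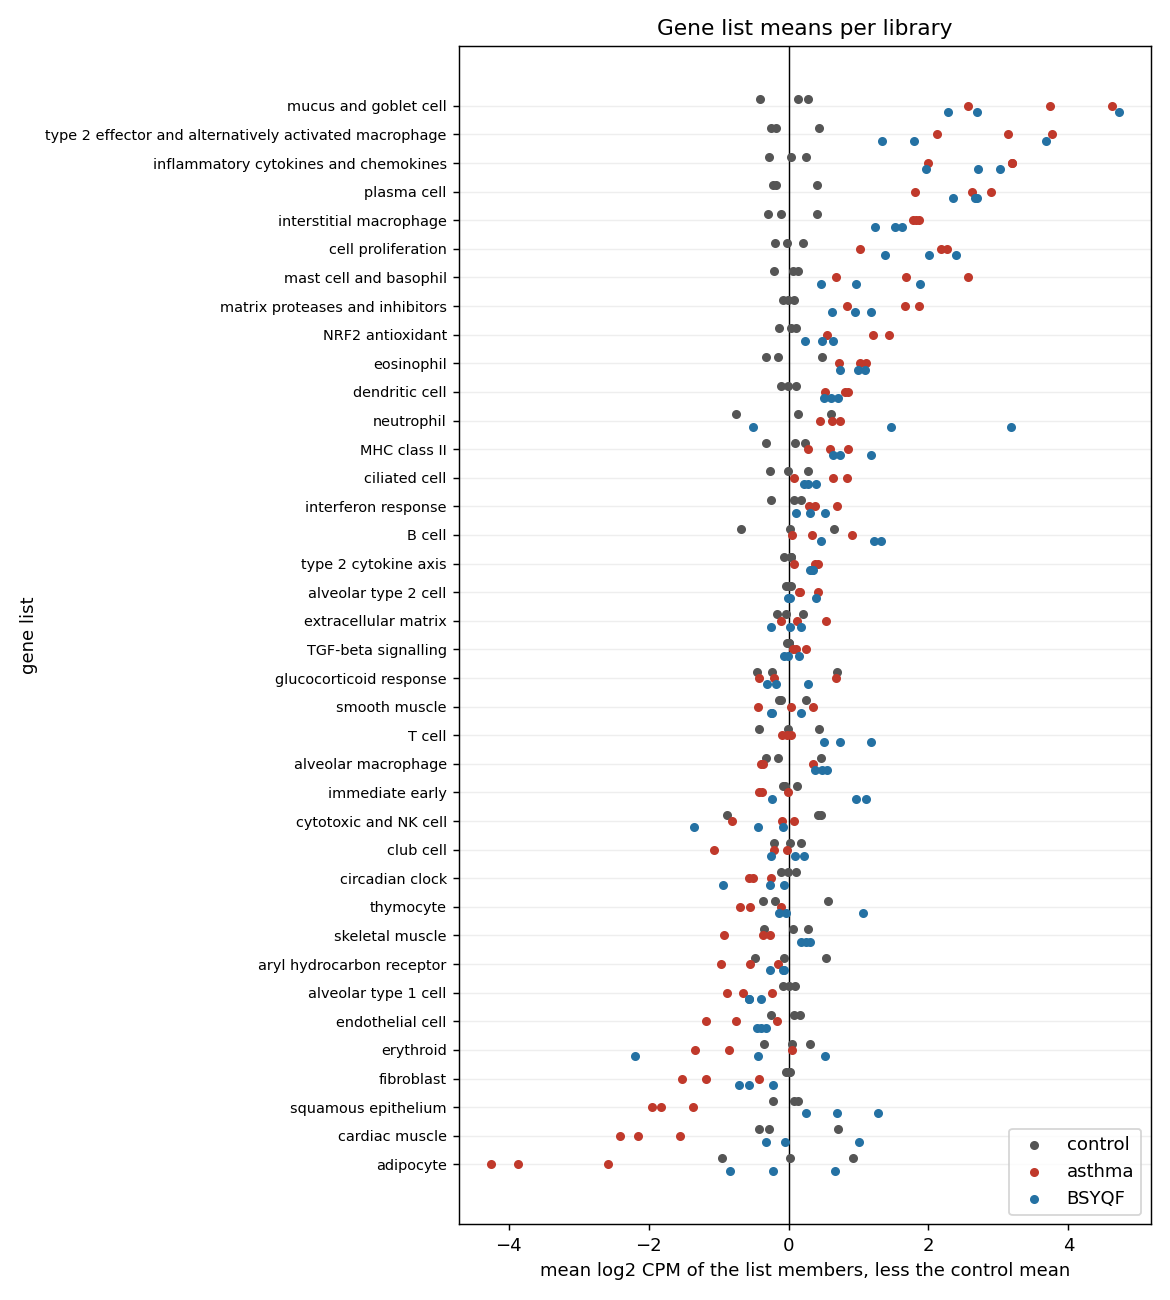
Mean log2 CPM of the members of each of 38 gene lists in each library, less the mean of the 3 control libraries, with a point per library and colours for the control, asthma and BSYQF groups. Cardiac muscle, adipocyte and squamous epithelium lists lay below every control and BSYQF library in each asthma library, and the plasma cell and interstitial macrophage lists lay above every control library in all 6 asthma and BSYQF libraries.

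The comparison of BSYQF with control asks how far the treated lungs still differed from normal lungs. Several antibody-secreting cell, macrophage, chemokine and proliferation genes were above control, and the list calls given below were lost with an estimated correlation. Jchain was at 3533 ± 133 CPM with BSYQF (4.94 ± 0.54, adjusted p = 0.00506), and Ms4a7, a membrane protein of macrophages on chromosome 19 from 11321039 to 11336146 on the minus strand, at 15.9 ± 3.92 CPM against 2.94 ± 0.643 in control (2.43 ± 0.25, adjusted p = 0.00506). Nuggc, a nuclear GTPase of germinal centre B cells, was at 6.94 ± 3.22 CPM against 0.0585 ± 0.101 in control (adjusted p = 0.00549). Il21, a cytokine of follicular helper T cells, rose from 0.0195 ± 0.0338 to 1.88 ± 0.587 CPM (adjusted p = 0.0214). Both had so few counts in control that no fold is given. Clca1 (9.86 ± 1.88, adjusted p = 0.0386), Muc5ac (4.43 ± 0.88, adjusted p = 0.0407) and Retnla (5.69 ± 1.06, adjusted p = 0.0338) were also higher than in control.

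By list, 4 of 12 mucus and goblet cell genes rose over all genes and 11 adjusted over the list alone, 3 and 9 of 14 type 2 effector genes, 6 and 7 of 8 plasma cell genes, and 5 and 7 of 8 interstitial macrophage genes. Of 16 inflammatory cytokines and chemokines 6 rose over all genes and 13 adjusted over the list alone, with the neutrophil attractants Cxcl1 at 2.88 ± 0.43 and Cxcl5 at 4.78 ± 0.87. Of 15 proliferation genes 10 rose over all genes and 15 adjusted over the list alone, with Top2a at 2.14 ± 0.29. These 6 lists rose with adjusted p = 8.1e-11, 5.9e-08, 8.1e-11, 8.7e-10, 1.3e-11 and 7.0e-16. The calls were lost at adjusted p = 0.29, 0.34, 0.16, 0.16, 0.16 and 0.29 with an estimated correlation. MHC class II genes rose (adjusted p = 2.7e-07; adjusted p = 0.29 with an estimated correlation), with 1 of 9 members rising over all genes, H2-Eb1 at 0.91 ± 0.19, and 9 adjusted over the list alone. B cell and T cell genes rose (adjusted p = 2.8e-05 and 7.4e-06; adjusted p = 0.41 and 0.29 with an estimated correlation), with none of their 10 and 10 members called over all genes and 5 and 7 rising adjusted over the list alone. Neutrophil, alveolar macrophage, dendritic cell, ciliated cell and immediate early genes rose with adjusted p = 0.0164, 0.0287, 0.0287, 0.0374 and 0.0203, and adjusted p = 0.59, 0.41, 0.29, 0.59 and 0.57 with an estimated correlation. Of their members 0 of 11, 1 of 12, 1 of 8, 0 of 14 and 0 of 11 rose over all genes. Adjusted over the list alone 6, 3, 4, 0 and 0 rose, and 1 dendritic cell gene fell. The neutrophil list mean lay -0.50, 1.47 and 3.17 from the control mean in BSYQF replicates 1, 2 and 3. The BSYQF and control libraries overlapped in the neutrophil, B cell, alveolar macrophage, ciliated cell and immediate early means.

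Lower than control were cytotoxic and NK cell genes (adjusted p = 0.0239; adjusted p = 0.59 with an estimated correlation), fibroblast genes (0.00445; adjusted p = 0.41 with an estimated correlation), alveolar type 1 cell genes (0.00257; adjusted p = 0.29 with an estimated correlation), endothelial genes (0.0112; adjusted p = 0.59 with an estimated correlation) and circadian clock genes (0.0323; adjusted p = 0.41 with an estimated correlation). No member of these 5 lists was called over all genes or adjusted over the list alone. The cytotoxic and NK list mean lay -0.89, 0.46 and 0.42 from the control mean in the control replicates and -0.08, -0.43 and -1.35 in the BSYQF replicates, with only BSYQF replicate 3 below every control. The clock list mean lay -0.93, -0.07 and -0.27 from the control mean in BSYQF replicates 1, 2 and 3, with replicate 2 inside the range of the controls and the largest fall in replicate 1. The genes that fell included Nrep (-1.11 ± 0.15), the phospholipase receptor Pla2r1 (-1.17 ± 0.24), Chn1 (-0.91 ± 0.18), the growth factor Pdgfb (-0.89 ± 0.17) and Fgf10, a growth factor of the lung mesenchyme (-0.80 ± 0.16). Cardiac muscle, adipocyte and squamous epithelium genes did not pass (adjusted p = 0.607, 0.937 and 0.115), nor did extracellular matrix genes (0.602) or NRF2 antioxidant genes (0.165). In the interferon response, TGF-beta and NRF2 lists, which did not pass, 1 member each rose over all genes. The median, mean and test differed in sign in the interferon response (median −0.04, mean 0.33), skeletal muscle (−0.16, 0.58), extracellular matrix (−0.0068, 0.0024), TGF-beta (−0.18, 0.04), club cell (−0.16, 0.04) and aryl hydrocarbon receptor (0.05, −0.21) lists, none of which passed.

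In BSYQF against control 246 genes were called, 240 higher and 6 lower, of 2330 with an unadjusted p under 0.05, and 212 of them changed at least 2-fold (210 higher, 2 lower). The groups did not overlap in 24.8% of genes, where chance gives 10%. DESeq2 called 806 genes and limma voom 917. Calls were 72, 17 and 9 without control replicate 1, 2 or 3, 146 and 563 without asthma replicate 1 or 3, and 135 without BSYQF replicate 2, and without BSYQF replicate 1 they were 101 higher and 1 lower. Of the 37 called genes the rule named, Jchain, Ms4a7 and Nuggc were called in every fit that left out a library, while Muc5ac was called in 4 of the 9 and Clca1 and Retnla in 3. The authors' deposited table listed 896 genes (773 higher, 123 lower), 620 of them with an adjusted p under 0.05 there. All 825 of them tested here had the same sign, and 211 were called here.

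Most genes that changed in asthma differed in the opposite direction between BSYQF and asthma. Of the 1213 genes that rose in asthma 1049 were lower with BSYQF than in asthma, and of the 656 that fell 643 were higher. Together 1692 of 1869, or 90.5%, had the opposite sign, 1 of them called (Krt5), and 0 were called with the same sign. Both comparisons share the asthma libraries, and with BSYQF libraries simulated as further asthma libraries 64.2% of the 3077 genes called on average had the opposite sign (61.3 to 65.8 over 30 draws). The covariance of the fold changes was −0.297 against −0.0638 simulated (−0.0817 to −0.0484). The simulation drew genes independently and so left out variation shared by the genes of a library. It also called more genes than the 1869 of the real libraries, so its values are not matched to them. The observed share was 74.2% without asthma replicate 2, of 248 genes called there. The slope of the BSYQF against control change on the asthma against control change was 0.641 over the called genes, against 0.929 simulated (0.907 to 0.945). By library the slope was 0.958, 1.03 and 0.623 for asthma replicates 1, 2 and 3, which also served to call the genes, and 0.727, 0.548 and 0.387 for BSYQF replicates 1, 2 and 3. Asthma replicate 3 thus lay within the range of the BSYQF libraries. The share of called genes on the control side of the asthma mean was 24.8, 10.2 and 94.5% in asthma replicates 1, 2 and 3. It was 69.4, 90.7 and 91.4% in BSYQF replicates 1, 2 and 3.

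Of the 1869 genes 223 were called the same way in BSYQF against control, 218 higher and 5 lower. Independent lists of these lengths would share 19.8 higher and 0.267 lower genes. With BSYQF libraries simulated as further asthma libraries, 2198 of 3077 were called in both on average (2137 to 2297). That simulation called more genes in asthma against control than the 1869 of the real libraries, so it was not matched to them. Its count is thus no firm value for the absence of a formula effect. The 223 became 675 with DESeq2 and 815 with limma voom, 62, 17 and 9 without control replicate 1, 2 or 3, 90, 125 and 529 without asthma replicate 1, 2 or 3, and 95 and 119 without BSYQF replicate 1 or 2. Over all genes, 81.9% had the same sign in both comparisons against control, beside 66.5% in unchanged simulated groups, and the covariance was 0.463 beside 0.0591. The 3 controls cannot be split into sets of at least 2 libraries each, so part of the excess may come from the shared controls.

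**Figure D3:**
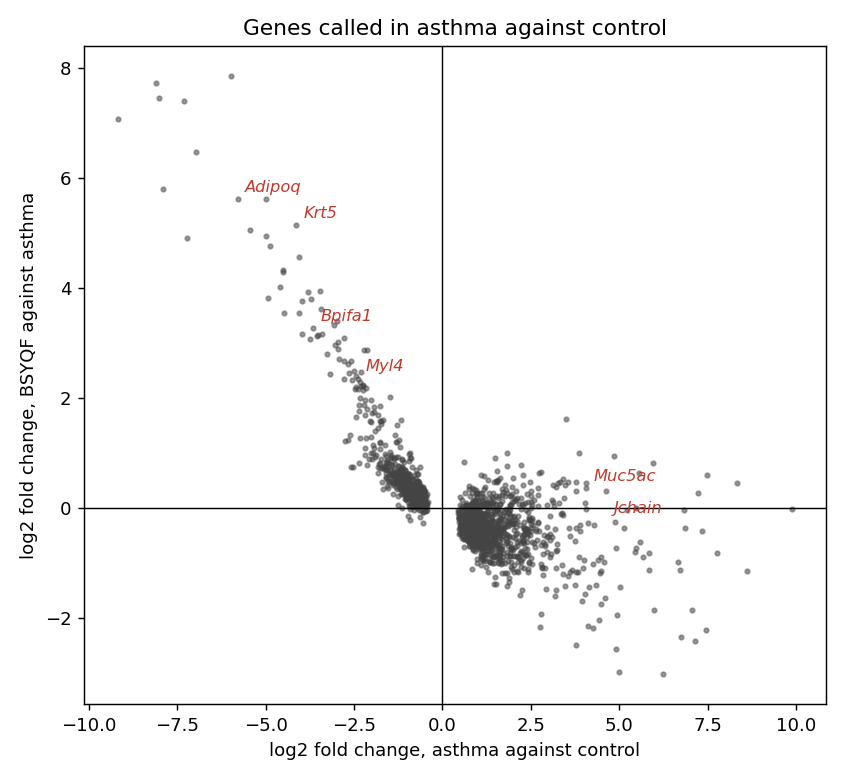
Log2 fold change in BSYQF against asthma (vertical axis) plotted against that in asthma against control (horizontal axis), with a point for each of the 1869 genes called in asthma against control. Of them 1692 lie in the upper left and lower right parts, where the signs are opposite; Krt5 and Bpifa1 lie at the upper left, Muc5ac and Jchain just above 0 at the right, and points beyond about −6 include genes with no count in the asthma libraries, whose fitted values are not measured folds.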

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

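All alternatives were planned except edgeR's newer dispersion method. In asthma against control, DESeq2 called 3258 genes and limma voom 4935 (1800 at least 2-fold), against 1869 and 1012. Omitting a library in turn gave 171 to 4262 calls, and 159 to 2094 at least 2-fold: 438, 182 and 357 without control replicate 1, 2 or 3, 171, 248 and 4262 without asthma replicate 1, 2 or 3, and 944 without BSYQF replicate 2. In BSYQF against asthma, against 1 call, an unadjusted p under 0.05 with a 2-fold change gave 353, DESeq2 122 (107 at least 2-fold) and a fit on the 6 libraries compared 0 (0 at least 2-fold), with 797 genes at an unadjusted p under 0.05 in that edgeR fit. Omissions gave 0 to 114, and 0 to 92 at least 2-fold, with 114 without asthma replicate 3, 1 without BSYQF replicate 2 and 0 without any other library (547 to 2260 at an unadjusted p under 0.05). In BSYQF against control, against 246 calls and 212 at least 2-fold, the unadjusted threshold gave 791, DESeq2 806 (532), limma voom 917 (425) and the 6 libraries 389. Omissions gave 9 to 563, and 9 to 365 at least 2-fold: 72, 17 and 9 without control replicate 1, 2 or 3, 146 and 563 without asthma replicate 1 or 3, 135 without BSYQF replicate 2, and 101 higher and 1 lower without BSYQF replicate 1. The genes called the same way in both comparisons against control, 223, became 675 with DESeq2, 815 with limma voom and 9 to 529 on omissions. The share with opposite signs, 90.5%, was 74.2% to 96.7% on omissions, lowest without asthma replicate 2. The slope of 0.641 moved by less than its spread over BSYQF libraries (SD 0.170) under all settings. Lists passing fell from 14, 15 and 19 to 0, 0 and 0 with an estimated correlation, and with fry to 1 in BSYQF against asthma and 9 in BSYQF against control. The erythroid list in BSYQF against asthma, not passing and lower by the test, was higher without BSYQF replicate 2 (adjusted p = 0.0308; 0.0308 to 0.999 on omissions). The cause was not tested for any of these, though fits with fewer libraries have fewer degrees of freedom by construction. Other scalings and filters and removal of antibody genes left all counts of calls within 1.5 times.

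With the replicate number as a block, the calls were 1469, 15 and 237 in asthma against control, BSYQF against asthma (15 at least 2-fold) and BSYQF against control. The 9 same-numbered pairs of libraries had correlations of their deviations from −0.259 to 0.339, with 2 over 0.1, and a library correlated best with its own number in 3 of 18 cases. No pairing by number was thus seen, but so few libraries cannot exclude one. Of values for named genes under the alternatives, 472 lost a call, 133 gained one and 0 turned direction while called. Il4, Il5, Il13 and Epx had too few counts to be tested.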

Other observations

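Tests of the tissue, library and clock patterns and the counts of splits were chosen after the results were seen. The test of Usp2 and Wee1 was chosen after the clock pattern was seen and before those genes were looked at. Several genes varied widely between the BSYQF libraries. Ngp and Camp, granule genes of immature neutrophils, reached 286 and 67.7 CPM at most in the BSYQF group against maxima of 3.24 and 1.99 in control, and did not pass the test (adjusted p = 0.121 and 0.127). The listed genes with symbols beginning with Igh, Igk or Igl together took 308 CPM of the library total in BSYQF replicate 3. They took 151.79 and 115 in replicates 1 and 2, 127, 141 and 65.2 in the asthma libraries, and 38.0 to 42.7 in control. The constant genes Igha, Ighg1, Ighg2b, Ighg3 and Ighe were not in the count table, so these values do not measure all antibody RNA. The natriuretic peptide gene Nppb stood at 11.6 CPM in BSYQF replicate 3 and at most 1.05 in every other library. The immediate early gene Egr1 was at 323 and 378 CPM in BSYQF replicates 1 and 2 and at 80.7 in replicate 3, against 111 to 126 in control.

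The cardiac muscle, adipocyte and squamous epithelium list means were low in all 3 asthma libraries. Of their 12, 7 and 4 measured members, 12, 5 and 3 were lower in asthma than in control and 0, 2 and 1 higher. With BSYQF the cardiac and adipocyte genes were near control. The squamous list mean lay 0.70, 0.26 and 1.28 above the control mean in BSYQF replicates 1, 2 and 3, against at most 0.14 in a control library. That list did not pass in BSYQF against control (camera adjusted p = 0.115). Muscle and keratin genes were 7 of the 10 with the smallest p-values in BSYQF against asthma. Dilution of resident tissue by infiltrating cells is argued against for the cardiac genes: the median log2 change of 74 genes of other resident cells in asthma was −0.222 (SD 0.816), against −2.03 for the cardiac list. Different amounts of heart or pulmonary vein muscle and of fat carried along in dissection may be part of the pattern, since cardiac genes varied together between libraries of a group (median correlation across member pairs 0.750) and so did adipocyte genes (0.650), each at percentile 100 of random lists matched on expression. That test cannot separate carried tissue from a real loss of such cells, since genes of a cell type vary together in either case. For squamous genes the value was −0.00363, with members near the floor, so tissue carried along and a change in the airway epithelium cannot be told apart; a change of muscle, fat or epithelium with the model and the formula was not tested and stays open.

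Asthma replicate 3 and BSYQF replicate 1 stood apart from their groups, and a split of the 6 libraries into asthma 1, asthma 2 and BSYQF 1 against the rest called 1989 genes where the real split called 1, which regroups the libraries by these positions and is no separate support for them. Library size is argued against for BSYQF replicate 1, whose total of 17352870 counts lay between those of the other BSYQF libraries (16947450 and 18007317). For asthma replicate 3, the deepest library, the number of counts is argued against too. Thinned with all libraries to one total, it stood at 1.69 on the first principal component (1.77 at full depth). It lay 61.4 from the mean of the other asthma libraries (62.2 at full depth), and thinning moved no library by much. An exchange of the labels of these 2 libraries stays open. On the first component asthma replicate 3 lay 10.96 from the mean of BSYQF replicates 2 and 3 and 62.2 from that of asthma replicates 1 and 2, and BSYQF replicate 1 lay 23.5 from the asthma and 49.7 from the BSYQF mean. On the second component each lay nearer its own group (7.61 against 38.3, and 7.70 against 53.6), so an exchange and other causes cannot be told apart. A difference between mice in how strongly the model took hold may explain these positions and was not tested. The share of genes with opposite signs, 90.5%, was 96.7% without asthma replicate 3.

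Of 12 clock genes looked at, 9 had their highest or lowest value of the 9 libraries in BSYQF replicate 1, each on the side a shift in time of day would give (2 of 3 high, 7 of 9 low), and 3 did not. Cry1, Cry2 and Bhlhe41, also tested members of the clock list, were not among the 12. Arntl was at 17.9 CPM there and at most 10.7 elsewhere, and its opposites Dbp and Nr1d1 were at 5.09 and 7.57 against at least 36.1 and 45.5 elsewhere. Lung taken at another time of day may be the cause. Usp2 and Wee1, clock output genes outside the fixed list whose prediction was written first, were 2 of 2 lowest in this library of the 9. They were at 16.8 and 13.7 CPM, against at least 18.3 and 20.2 elsewhere, so Usp2 was lowest by a small margin. Both were chosen as genes that move with Dbp, so this test cannot separate time of day from other causes of a clock shift. Loss of short-lived transcripts is argued against, since the immediate early list mean there was 0.960 above control on the log2 scale, and the highest control library was at 0.124. That mean was also raised in BSYQF replicate 2 (1.11), so a rise of these genes could hide a loss, which is not excluded. Hours of dissection are not given in the sources used here, and an effect of the formula on the clock was not tested.

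Splits of 3 against 3 libraries number 10, which is too few for a share under 0.05. In asthma against control 1 split, the real one, gave as many as its 1869 calls (highest other 0, with edgeR), and 2 gave as many as its 14 lists (highest other 18). In BSYQF against asthma 3 splits gave at least 1 call (highest other 1989), and 2 gave as many as 15 lists (highest other 18). In BSYQF against control 1 split gave as many as 246 calls (highest other 0, with edgeR) and 1 as many as 19 lists (highest other 15).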
